A study of Mus musculus with 3 samples.

How the data were processed

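RNA sequencing of 3 libraries was analysed, each from cortical astrocytes of 1 wild-type mouse pup. Per the labels, RNA was isolated with a column miniprep kit and libraries were prepared with a stranded poly(A) mRNA kit. The sample titles and the design text give the age as postnatal day 1, whereas the sample descriptions use a name for day 0, and the titles were followed. Pups 5, 6 and 8 are replicates 1, 2 and 3 of a single group, and the labels name them biological replicates. The sex of the pups is not given in the labels used here. Transcripts of most replication-dependent histone genes lack a poly(A) tail, so a poly(A) library counts them only in part.

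The deposited table gives a signal per gene, a normalized read count for 19471 genes in each library, together with the authors' mean of the 3, which was not used in any test. Per the submitters' processing notes the values were normalized with DESeq2 and the genome build was mm10. The aligner, the counting tool and its strand setting, the annotation release, the read length and the filter on genes are not given in the sources used here. The values are not divided by gene length. A library's values were whole multiples of what 1 read is worth (0.81, 0.47 and 1.2 for replicates 1, 2 and 3), so whole reads were recovered for 100% of the values within a tolerance of 0.05 reads. The library totals were 14380993, 25128038 and 9858626 reads, a 2.55-fold range, and the size factors 1.23, 2.12 and 0.836. Their geometric mean was 1.30, and each was 1.29 times the median-of-ratios factor computed from these 3 libraries alone, which leaves open whether other libraries or genes entered the authors' scaling. A common factor leaves the ratios of values as they are, but with a pseudocount of 1 and a fixed floor it moves the log2 contrasts that involve low genes. With values rescaled to CPM, which are smaller, the difference between the astrocyte and erythroid medians was 8.21, and that between the astrocyte and oligodendrocyte medians 8.07. The count of 0 reads allows up to 3 reads, which is a normalized count of 2.44, 1.42 or 3.59 in replicates 1, 2 and 3. Mitochondrial genes took 0.723% to 1.14% of the reads.

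Gene identifiers were matched to GENCODE vM21 on the same build, which held 19366 of them (99.5%) and gave biotype, position and exon length. The symbol was blank for 2570 genes, and 2465 of these were named from that annotation. The values were log2-transformed after adding a pseudocount of 1, so a fold of a low gene is understated. Genes with a mean of 10 or more were counted as detected, and variation between libraries was described for genes with a mean of 100 or more. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16 were used.

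The tests, the 23 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Named are H2bc21 and each member of the histone variant list, the 3 members of each list with the highest mean and the 3 lowest of the astrocyte list, the 15 most abundant genes, the 10 genes with the largest SD of log2 values among those with a mean of 100 or more, and the sex-linked list. The few other genes named were chosen after their values were seen, and some genes that the rule selects are not reported here. List members without a row in the table were not analysed here.

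The astrocyte list was compared with each of 10 other cell type lists by a two-sided permutation test of the difference in median across genes, with 100000 resamples, or exactly for the erythroid list, and Benjamini-Hochberg adjustment over the 10 lists. The smallest p it can give is 1e-05. The alternative that keeps only members with a mean of 10 or more was applied to both lists of a pair. State and function lists were placed among 10000 random lists drawn from 17896 genes with a mean of 1 or more. Histone genes were compared with H2bc21 by an intercept-only limma model with a trended prior on the within-library log2 difference, adjusted over 13940 genes. Reads of each gene were compared between libraries by a chi-square test with expected reads from the library totals, for genes with a mean of 10 or more and at least 30 reads in all, and edgeR gave the biological coefficient of variation. All tests describe these 3 cultures. The histone p-values rest largely on a spread that limma pools over genes, and they do not measure the spread of each gene alone. Every difference also shares the same 3 values of H2bc21. The chi-square p-values set the spread between libraries against read sampling alone.

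The procedures were tested on simulated data with the depths and means of these libraries. For the comparison of reads between libraries, run on 14469 genes, the chi-square test called 97% of genes changed 1.5-fold and 100% of those changed 3-fold, with 15 false calls. For the list comparison, run on 17896 genes, the permutation test called 6% of list pairs with no shift and 82% with a log2 shift of 4. For the histone comparison, over 50 simulated data sets of 13930 genes, limma called 8.16% of genes with the level of the reference gene where 5% were intended, and 99.96% of genes at 2-fold. The cause of the excess was not tested. An alternative with separate variances, chosen after that test, called 5.54% and 100%, and edgeR with the reads of H2bc21 as an offset called 8.78% and 100%. On the real data both alternatives gave the same counts of 11 histone genes above and 9 below.

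The alternatives were another pseudocount, other filters, list means, values per kilobase of exon, values rescaled to CPM (equal library totals), TMM scaling, limma without a trend and each replicate left out in turn. Added after the data were seen were expected reads from the size factors, the edgeR test on recovered reads, limma with separate variances, and the removal of the 2 most abundant members of each other list. Shared sequence was measured as the share of 50-base stretches of a histone transcript found in another annotated gene. Of 108 named and histone genes checked, 26 overlapped another gene of the table.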

Results

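Gene expression was measured by poly(A) RNA sequencing in cortical astrocytes that were isolated from wild-type mouse pups at postnatal day 1 and kept in culture for 7 days before the RNA was collected. The series concerns H2BE, a variant of the core histone H2B, and its effects by age and cell type. The libraries analysed here form 1 group of 3 biological replicates, numbered 1, 2 and 3, from pups numbered 5, 6 and 8. Summed over genes, replicate 1 held 14380993 reads, replicate 2 held 25128038 and replicate 3 held 9858626. With a single group there was no contrast between genotypes or ages, so each comparison was made between genes within the libraries or between the libraries themselves. Values are the deposited normalized read counts, given as mean ± SD over the 3 replicates, and they were not divided by transcript length.

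The most abundant transcripts included those of the intermediate filament genes Vim and Gfap. Pea15a, which encodes a death-effector-domain phosphoprotein abundant in astrocytes, ranked 1 with a normalized read count of 96144 ± 2941 (SD, n = 3). It was followed by Igfbp5, an insulin-like growth factor binding protein, at 90346 ± 15594, by Vim at 83438 ± 3538, and by the matricellular protein gene Sparc at 70894 ± 2879. Gfap, the intermediate filament of astrocytes, stood at 52283 ± 6679 and ranked 5. The lipid carrier gene Apoe reached 51612 ± 10042, the smooth muscle actin gene Acta2 48318 ± 806, the actin gene Actb 45147 ± 1975 and the brain creatine kinase gene Ckb 40965 ± 5374. The remaining 6 of the 15 most abundant genes lay between 34237 and 36612, and they were the mitochondrial gene COX1, the lysosomal genes Ctsd and Psap, Eef1a1, Tmsb4x and the fatty acid desaturase gene Scd2. The 10 most abundant genes took 5.19% to 5.28% of the reads of a library. In all, 13941 genes had a mean normalized count of 10 or more, 13074 of them protein-coding, and 10571 genes had a mean of 100 or more.

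The first comparison asked how far markers of astrocytes stood above markers of other cells that a cortical culture could hold. Of the 24 astrocyte markers, 23 had a mean of 10 or more and 19 a mean of 1000 or more. The highest were Gfap, the secreted chaperone gene Clu at 29125 ± 2573 and the membrane protein gene Mlc1 at 26911 ± 1801. The lowest were the neurotensin receptor gene Ntsr2 at 133 ± 5.28, the calcium-binding protein gene S100b at 68.7 ± 19.4, and the connexin gene Gjb6 at 2.95 ± 0.583, which rested on 3 to 6 reads per library. The median of the astrocyte list was 12.15 on the log2 scale, and it lay above the median of each of the 10 other cell type lists in 3 of 3 libraries.

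**Figure D1:**
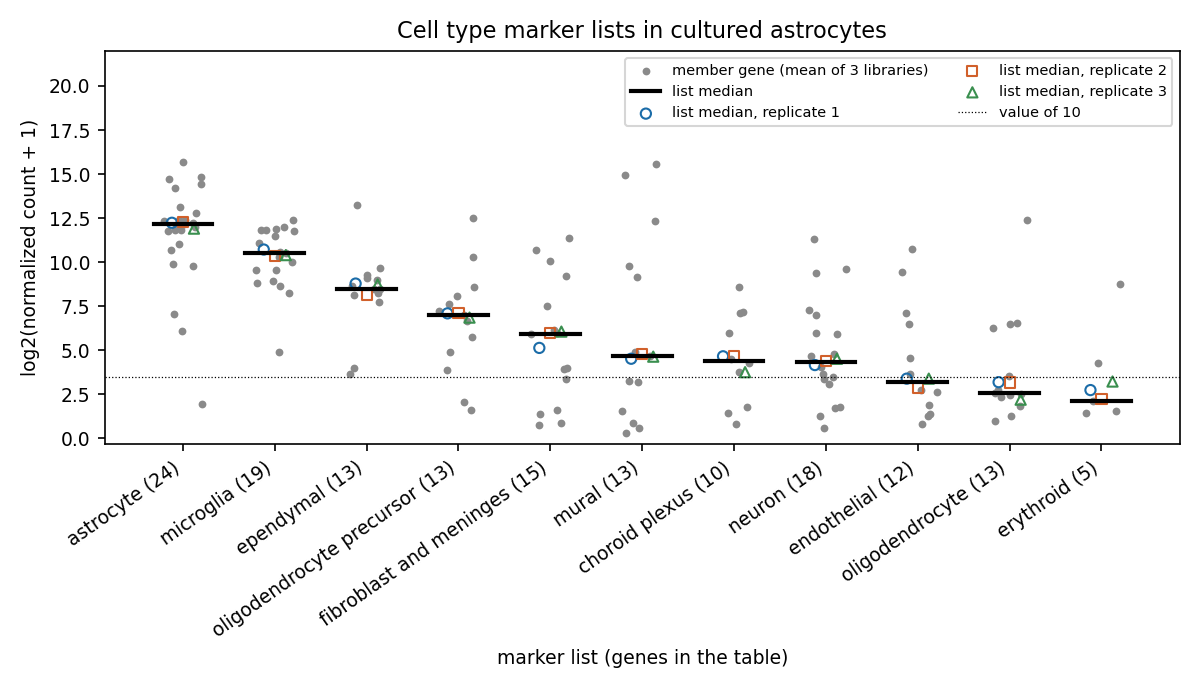
Log2 of the normalized read count plus 1 (vertical axis) for the genes of 11 cell type marker lists (horizontal axis, with the number of genes in the table). Grey points are genes averaged over the 3 libraries, black bars are list medians, open symbols are the list medians of each replicate and the dotted line marks a value of 10. The astrocyte median of 12.15 lies above the others, of which the microglial median of 10.53 is the nearest.

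Microglial genes came closest to the astrocyte list. All 19 microglial genes in the table had a mean of 10 or more, and 12 had a mean of 1000 or more. The growth factor receptor gene Csf1r stood at 5517 ± 1362, the cathepsin gene Ctss at 4114 ± 482 and the complement gene C1qa at 3845 ± 936. The astrocyte median exceeded the microglial median by 1.62 on the log2 scale, or 3.07-fold, with a mean over libraries of 1.65 ± 0.24 (adjusted p = 0.0114, two-sided permutation test across genes). That call ended when list means replaced medians, where the difference was 1.32 (adjusted p = 0.10 in the permutation test), and when values were divided by exon length, where it was 0.90 (adjusted p = 0.334 in the permutation test). Over the 9 alternatives the adjusted p ranged from 0.00749 to 0.334.

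Genes of ciliated ependymal cells were also expressed. All 13 ependymal list genes in the table had a mean of 10 or more, led by Foxj1, the master transcription factor of motile cilia, at 9966 ± 1517, and by the axonemal genes Rsph1 at 827 ± 207 and Cfap44 at 631 ± 175. Their median lay 3.65 below the astrocyte median on the log2 scale (adjusted p = 0.0017, permutation test across genes). Among 13 oligodendrocyte precursor genes, 11 had a mean of 10 or more, and the transcription factor genes Olig1 at 5896 ± 1027 and Olig2 at 1240 ± 102 and the receptor gene Pdgfra at 390 ± 91.5 were the highest. The precursor list lay 5.15 below the astrocyte list (adjusted p = 0.0017, permutation test). Of 13 genes of mature oligodendrocytes, 5 had a mean of 10 or more. Cnp stood at 5371 ± 414, while the myelin gene Mal was at 89.7 ± 3.06, and the list median was 9.59 below that of astrocytes (adjusted p = 0.000375, permutation test), or 5.68 below with only those 5 members.

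Neuronal markers were low as a list, with single members well above it. Of 18 neuronal genes, 12 had a mean of 10 or more, and the list median was 7.80 below the astrocyte median (adjusted p = 0.0002, permutation test across genes). Map2, which encodes a microtubule-associated protein, stood at 2564 ± 55.0, the kinase gene Camk2a at 776 ± 85.7 and the tubulin-binding protein gene Stmn2 at 669 ± 129. The vesicle protein gene Snap25, named after its value was seen, had a mean of 2.51 ± 0.691. Endothelial genes lay 8.95 below the astrocyte list (adjusted p = 0.0003, permutation test), with 6 of 12 at a mean of 10 or more, and 5.38 below with only those 6. Their highest members were the organic anion transporter gene Slco1a4 at 1692 ± 153, the receptor gene Kdr at 690 ± 59.6 and Itm2a at 138 ± 14.5, whereas Pecam1, the gene of an endothelial adhesion molecule and also named after its value was seen, stood at 5.43 ± 1.54.

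The mural list ranged from very abundant genes to members near the floor. Acta2, Tagln at 31716 ± 1419 and Cnn1 at 5112 ± 366, which encode proteins of the contractile apparatus, were the highest. Of the members named after their values were seen, the receptor genes Pdgfrb and Notch3 stood at 900.2 ± 99.2 and 581 ± 122, the smooth muscle myosin gene Myh11 at 24.5 ± 2.12, and the potassium channel genes Kcnj8 and Abcc9 at 1.01 ± 0.884 and 0.586 ± 0.511. The list median was 7.48 below the astrocyte median (adjusted p = 0.00117, permutation test across genes). With only the 7 members at a mean of 10 or more the difference was 2.38 and the call ended (adjusted p = 0.0562 in the permutation test). The adjusted p ranged from 0.00065 to 0.0562 over the 9 alternatives.

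Fibroblast and meningeal genes lay 6.20 below the astrocyte list (adjusted p = 0.0003, permutation test across genes). Of the 15 in the table, 10 had a mean of 10 or more, and the highest were Islr at 2691 ± 422, the proteoglycan gene Ogn at 1658 ± 220 and the collagen gene Col1a2 at 1072 ± 94.2. Choroid plexus genes lay 7.75 below (adjusted p = 0.00038, permutation test), with the folate receptor gene Folr1 at 382 ± 45.5, the transthyretin gene Ttr at 201 ± 309 and Sostdc1 at 145 ± 14.5. Of the erythroid list, 5 genes were in the table, and 2 of them had a mean of 10 or more. Ermap was at 18.7 ± 2.86, while Klf1, an erythroid transcription factor, was at 3.64 ± 1.79. The erythroid median was 10.003 below that of astrocytes (adjusted p = 0.00416, exact permutation test), a median that is the value of Klf1 with 2 to 7 reads per library, and 5.66 below with only the 2 members at a mean of 10 or more. These p-values compare genes, which are not independent replicates, and across the 3 libraries an exact sign-flip test cannot give a p below 0.25.

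The state of the cultures was described with 11 further gene lists, each set against 10000 random lists of the same size, with no test between groups. Neural progenitor genes had a median of 10.40 ± 0.05 on the log2 scale over libraries, at the 99.99 percentile of random lists. Besides Vim, the intermediate filament gene Nes stood at 33920 ± 1314 and the fatty acid binding protein gene Fabp7 at 11035 ± 1066. All 16 cell cycle genes had a mean of 100 or more. The list lay at the 99.8 percentile, with the topoisomerase gene Top2a at 3751 ± 457, the proliferation marker gene Mki67 at 3571 ± 398 and the kinase gene Cdk1 at 1521 ± 138.

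Genes tied to reactive astrocytes lay at lower percentiles than the progenitor and cell cycle lists. The pan-reactive list was at the 57.7 percentile, with the sphingosine phosphate receptor gene S1pr3 at 5676 ± 60.4, the ceruloplasmin gene Cp at 2067 ± 373 and the adhesion receptor gene Cd44 at 1221 ± 129. It did not hold Gfap or Vim, which were placed in the astrocyte and progenitor lists, so its percentile leaves out these abundant genes. The A1 list, named for astrocytes activated by inflammation, was at the 68.3 percentile, led by the class I histocompatibility gene H2-D1 at 1852 ± 356, Fbln5 at 1767 ± 334 and Ggta1 at 1585 ± 82.1. The A2 list, named for astrocytes after ischaemia, was at the 92.3 percentile, led by Cd109 at 2419 ± 181, Emp1 at 2408 ± 136 and S100a10 at 1970 ± 379. Whether the lists differed from one another was not tested.

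Transcripts for secreted proteins that act on synapses, in a list that also held the receptor genes Megf10 and Mertk, were abundant. All 12 genes of that list had a mean of 100 or more, and the list reached the 99.8 percentile, with Sparc, the thrombospondin gene Thbs1 at 21138 ± 1042 and the glypican gene Gpc4 at 10054 ± 956. Genes of synapses themselves were at the 28.9 percentile, led by the glutamate receptor gene Gria1 at 1546 ± 211 and by the vesicle protein gene Vamp2 at 1037 ± 74.1. The cholesterol list was at the 99.95 percentile, led by the cholesterol exporter gene Abca1 at 9637 ± 403 and the synthesis enzyme genes Hmgcs1 at 4762 ± 551 and Sqle at 3690 ± 149. Immediate early genes were at the 95.1 percentile, with Jun at 2088 ± 137, Egr1 at 2085 ± 231 and Fos at 1394 ± 137. Histone chaperone genes were at the 99.7 percentile, with the FACT subunit gene Ssrp1 at 3877 ± 140 and the nucleosome assembly genes Nap1l1 at 2665 ± 624 and Nap1l4 at 2468 ± 96.7. The histone variant list was at the 99.3 percentile.

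The gene for H2BE, H2bc21 (also named Hist2h2be, ENSMUSG00000068854), was detected in each library. In mm10 it lies on chromosome 3 from 96221119 to 96223738 on the plus strand, as a single exon of 2620 nucleotides. Its normalized count was 196 in replicate 1, 213 in replicate 2 and 286 in replicate 3, a mean of 232 ± 47.6 (SD, n = 3) from 932 reads in all. This ranked 8400 among all genes and at the 39.7 percentile of genes with a mean of 10 or more. The SD of its log2 values over the 3 libraries was 0.28, at the 85.2 percentile of genes of similar mean, that is 0.5 to 2 times its own. No stretch of 50 bases of its transcript was shared with another annotated gene.

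H2bc21 was compared with the other histone genes to ask where the variant stands among them. Most replication-dependent histone transcripts lack a poly(A) tail and were counted only in part, so the ranks are of poly(A) reads. Of 55 histone entries in the table, 34 had a mean under 10 (with these included, 43 lay below H2bc21). The entries under 10 include pseudogenes, such as H3f3a-ps1 and H2ac14-ps, and the antisense gene H3f3aos. Of the 20 others tested beside H2bc21, 11 lay above it and 9 below it at an adjusted p under 0.05 (limma on within-library differences). Among all 13940 genes the same test placed 7379 above H2bc21 and 4596 below it, so such calls are not particular to histone genes. The histone counts were also 11 and 9 adjusted over the list alone. The replacement histone gene H3f3b was the highest at 4771 ± 107, a log2 difference of 4.38 ± 0.21 (SE), followed by the linker histone genes H1f0 at 2778 ± 212 and H1f2 at 2208 ± 203, Macroh2a1 at 2022 ± 85.4, and the H2A.Z genes H2az2 at 1850 ± 99.6 and H2az1 at 1647 ± 166. H3f3a stood at 1237 ± 122 and H2ax, whose product marks DNA breaks once phosphorylated, at 704 ± 110. The centromeric variant gene Cenpa at 446 ± 26.2 lay 0.96 above H2bc21 on the log2 scale and Macroh2a2 at 365 ± 13.9 lay 0.67 above it.

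**Figure D2:**
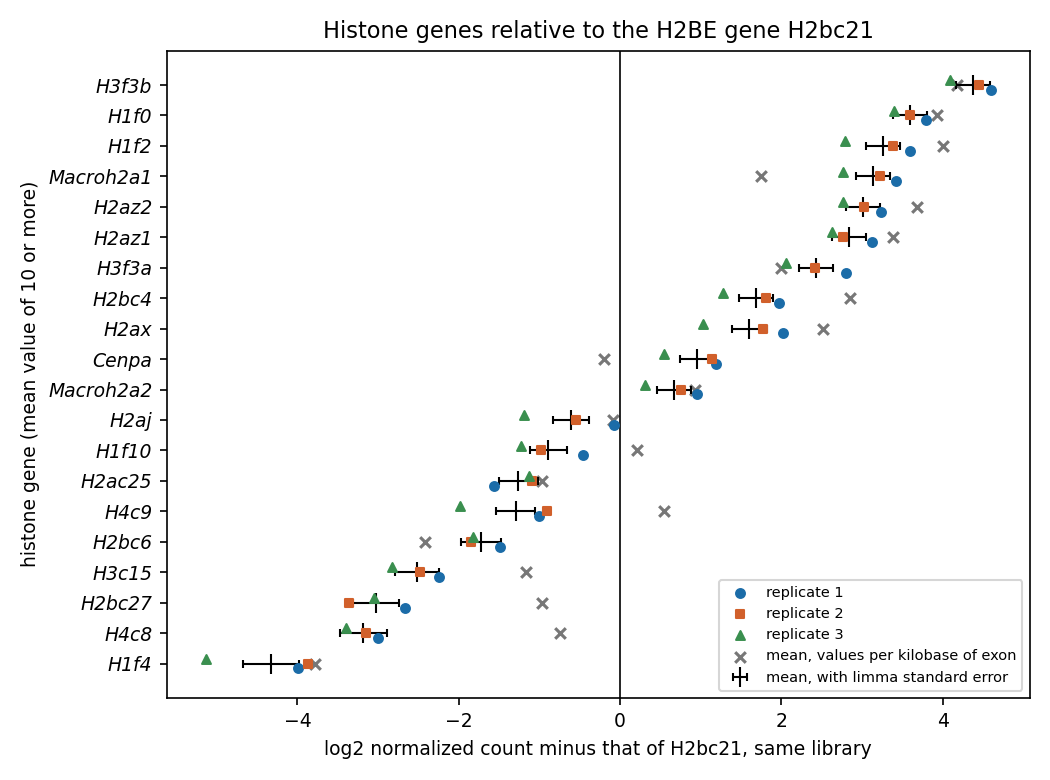
Log2 normalized read count of each of 20 histone genes minus that of H2bc21 in the same library (horizontal axis), for the genes with a mean of 10 or more (vertical axis). Coloured symbols are the 3 replicates, black bars the mean with its limma standard error, and grey crosses the mean after division by exon length. H3f3b lies 4.38 above H2bc21 and H1f4 has a difference of -4.33, and the cross of H4c9 lies on the other side of 0 from its mean.

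Among the genes of histone H2B, the transcript with the most reads was not H2bc21 but H2bc4, at 739 ± 41.0, a log2 difference of 1.69 ± 0.21 (adjusted p = 3.09e-15, limma) or 3.22-fold. With separate variances the adjusted p was 5.46e-07 (limma). H2bc21 gave 18.01% of the H2B reads in replicate 1 (95% Wilson interval 16.05% to 20.2%), 20.02% in replicate 2 (18.4% to 21.7%) and 25.8% in replicate 3 (23.1% to 28.8%), intervals that cover counting error only. H2bc4 gave 69.1% of the H2B reads over all libraries. These shares are of reads in poly(A) libraries, which count H2B transcripts without a poly(A) tail only in part. They were also not divided by length, and H2bc21 has 2620 nucleotides of exon against 1156 for H2bc4. Per kilobase of exon, the log2 differences from H2bc21 were 2.86 for H2bc4, -0.97 for H2bc27 and -2.42 for H2bc6. The read shares are therefore not shares of transcripts. Below H2bc21 were H2aj at 152 ± 31.0, H1f10 at 124 ± 17.5 and the H2B gene H2bc27 at 27.8 ± 7.12, with log2 differences of -0.61, -0.89 and -3.03. The lowest of those tested was H1f4, with a difference of -4.33. H2bc4 shared 30.1% of its 50-base stretches with other genes, and H1f4 and H2bc6 overlap on the same strand, so these values are uncertain.

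The histone calls rested on reads that were not corrected for length. After division by exon length, Cenpa and H1f10 changed sign with no call, the call of H2aj ended, and H4c9 lay 0.54 above H2bc21 (adjusted p = 0.0153, limma). Leaving out replicate 1 or replicate 2 ended the call of Macroh2a2, and leaving out replicate 2 ended those of H1f10 and H2aj.

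The SDs given with the means above are the spread between the 3 libraries. Each library came from 1 pup, so animal, culture and library preparation cannot be told apart. The permutation p-values compare genes, and the limma errors rest largely on a spread pooled over genes. Between pairs of libraries, Pearson's correlation across genes was 0.986 for replicates 1 and 2, 0.981 for 1 and 3 and 0.985 for 2 and 3, and Spearman's rho was 0.991, 0.987 and 0.990. The median over genes of the SD of log2 values was 0.161, and 91.5% of the genes with a mean of 100 or more had an SD under 0.3. The reads of 7726 of 13941 genes, or 55.4%, differed between libraries by more than read sampling (chi-square test, adjusted p under 0.05). With 1 replicate left out the number was 4958 without replicate 1, 5415 without replicate 2 and 5156 without replicate 3. The common biological coefficient of variation was 13.1% in edgeR. No pair of libraries matched within sampling noise, with a chi-square per degree of freedom of 13.8, 14.4 and 12.2.

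Of the 10571 genes with a mean of 100 or more, 11 had an SD above 1, and 5 of these were members of the sex-linked list. Among genes with a mean of 10 or more the number was 58. Xist, the non-coding RNA that coats the inactive X chromosome, had a normalized count of 3000 in replicate 1, 0.47 in replicate 2 and 4.78 in replicate 3. The Y-chromosome genes ran the other way. Ddx3y was at 0.81, 688 and 936 in replicates 1, 2 and 3, while Kdm5d, Eif2s3y and Uty had 0 reads in replicate 1, where the floor of 3 reads corresponds to a normalized count of 2.44. In replicates 2 and 3, Kdm5d stood at 539 and 536, Eif2s3y at 382 and 361, and Uty at 231 and 170. Tsix, the antisense partner of Xist, was below 1 in each library.

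The other named variable genes lay on autosomes. Ttr was at 557 in replicate 2 against 31.7 in replicate 1 and 13.2 in replicate 3, a 17.5-fold and a 42.3-fold difference. The synaptotagmin gene Syt1, which encodes a calcium sensor of synaptic vesicles, was at 222 and 244 in replicates 1 and 3 and at 35.9 in replicate 2, a 6.80-fold range. The other 3 were poorly characterised gene models. The pseudogene Gm11942 was at 216, 1.89 and 179 in replicates 1, 2 and 3, Gm10800 at 614, 52.8 and 182, and Gm15564, which is antisense to other genes, at 377, 822 and 53.8. Reads of pseudogenes, of antisense genes and of overlapping genes are uncertain, because how the authors' counting treated them is not given in the sources used here.

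Marker lists of other cell types also moved between the libraries, a comparison chosen after the values were seen. All 13 ependymal genes were lower in replicate 2 than in both other libraries, with a median log2 ratio to the mean of the others of -0.65. Of 19 microglial genes, 16 were higher in replicate 1 than in both others, with a median ratio of 0.43. Of 23 astrocyte genes with a mean of 10 or more, 17 were lowest in replicate 3, with a median ratio of -0.13. For a gene without differences the share by chance is 33.3% at equal depths. Of all 13941 genes with a mean of 10 or more, 3848 were lowest in replicate 2, 4903 highest in replicate 1 and 5233 lowest in replicate 3. Among the other lists, 8 of 11 oligodendrocyte precursor genes were lowest in replicate 3 (median ratio -0.40). Of 10 fibroblast and meningeal genes, 8 were highest in replicate 2 (median ratio 0.31).

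**Figure D3:**
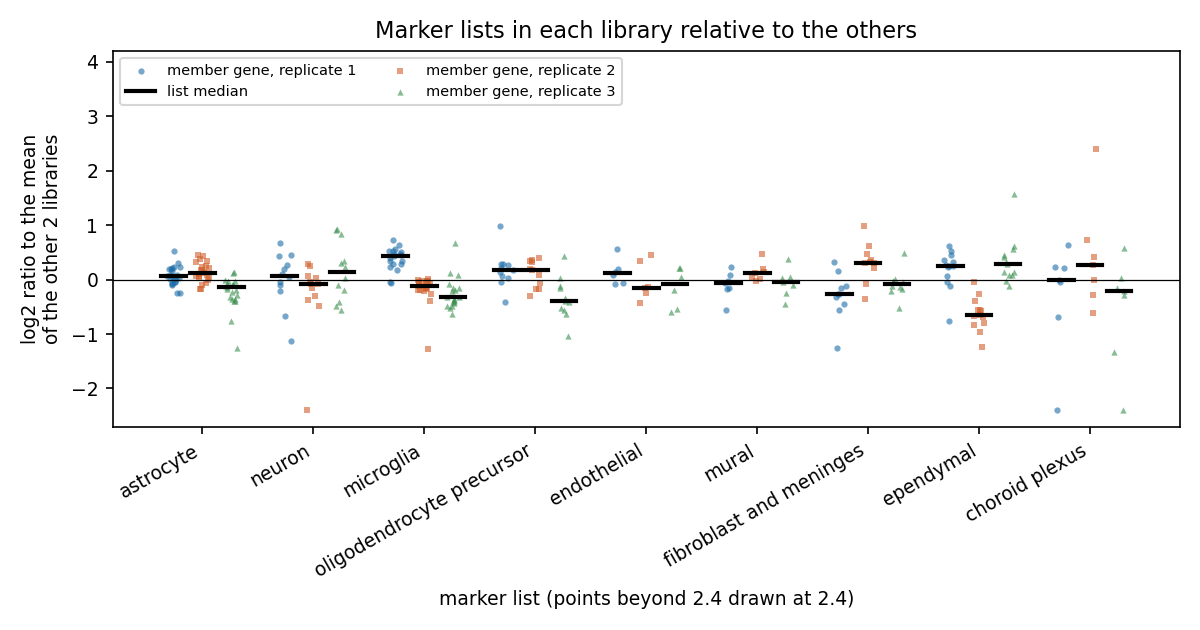
Log2 ratio of each gene's normalized count in 1 library to the mean of the other 2 libraries (vertical axis), for 9 cell type marker lists (horizontal axis) and members with a mean of 10 or more. Points are genes coloured by replicate and black bars are list medians. The ependymal genes of replicate 2 lie at a median of -0.65 and the microglial genes of replicate 1 at 0.43.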

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

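No paired analysis was possible because the libraries form 1 group. A contrast was taken as kept if its direction and side of the threshold held. A count was taken as kept within 1.5-fold of its main value, and any other value if it moved by less than the spread. Across the alternatives, 136 values of the main results were kept, 11 moved by more, 3 lost their call and 0 reversed. Among values of single genes and lists these numbers were 626, 9, 5 and 3. Of the 10 contrasts with the astrocyte list, 8 kept their call under each alternative run. The difference from the mural list was 2.38 with only members at a mean of 10 or more (adjusted p = 0.0562, permutation test), which removed its low members. The difference from the microglial list was 1.32 with list means (adjusted p = 0.10, permutation test) and 0.90 per kilobase of exon (adjusted p = 0.334, permutation test), and the cause was not tested. Per kilobase, H2bc21 had a log2 level of 6.46, and Cenpa at -0.20 (adjusted p = 0.396, limma), H1f10 at 0.21 (adjusted p = 0.358) and H4c9 at 0.54 (adjusted p = 0.0153) lay on the other side of H2bc21, since their exon lengths differ from its own. Adjusted p ranged over 9 alternatives from 1.46e-19 to 0.396 for Cenpa, 1.69e-05 to 0.358 for H1f10 and 3.46e-08 to 0.0153 for H4c9. With all genes above 0 there were 43 histone entries below H2bc21, pseudogenes among them, since 34 more were tested. The number with an SD above 1 was 58 among genes with a mean of 10 or more, where low counts add to the spread, and the chi-square test called 6814 of the genes with a mean of 100 or more. The median SD was 0.216 over all genes above 0, and the lowest Pearson correlation was 0.986 with values rescaled to CPM, the cause of which was not tested. With each replicate left out in turn the lowest Pearson correlation ranged from 0.981 to 0.986, the median SD from 0.114 to 0.154, and the number of genes whose reads differed beyond sampling from 4958 to 5415. The lowest of these counts, without replicate 1, was more than 1.5 times below the 7726 of all libraries. Leaving out replicate 1 or 2 ended the call of Macroh2a2 (adjusted p = 0.129 and 0.153, limma), and leaving out replicate 2 ended those of H1f10 (adjusted p = 0.0555) and H2aj (adjusted p = 0.149). Depth limits the genes near the floor, since replicate 3 had 9858626 reads, the fewest of the 3.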

Other observations

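Homeobox and other regional genes of the dorsal forebrain were expressed, and those of more caudal regions were near the floor. In lists chosen after the data were seen, 7 of 8 dorsal forebrain genes had a mean of 10 or more, with the LIM homeobox gene Lhx2 at 1354 ± 49.5 (SD, n = 3), Nr2f1 at 1016 ± 81.6 and Emx2 at 453 ± 137 (2 of the 8, Lhx2 and Emx2, are also in the progenitor list). Of 7 ventral forebrain genes in the table, 3 reached that level, with the interneuron genes Dlx1 at 84.2 ± 10.9 and Dlx2 at 79.1 ± 10.4. All 5 midbrain and hindbrain genes in the table were below 10, the highest being Irx3 at 4.91 ± 0.732.

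Contractile genes and genes of the insulin-like growth factor system were described in lists also chosen after the data were seen, with no test of either list. The 12 contractile and actin-binding genes of that list had means of 1760 or more, but it leaves out the smooth muscle myosin gene Myh11 of the mural list, at 24.5 ± 2.12. Besides Acta2 and Tagln the filamin gene Flna stood at 32699 ± 2522, the calponin gene Cnn3 at 16368 ± 2094 and Actn1 at 10163 ± 283. In the insulin-like growth factor system the binding protein genes Igfbp5, Igfbp2 at 24553 ± 1601 and Igfbp3 at 5259 ± 674 were above the receptor gene Igf1r at 732 ± 31.2 and the ligand genes Igf1 at 635 ± 56.6 and Igf2 at 66.6 ± 32.9. The other members were the receptor gene Igf2r at 822 ± 76.3 and the binding protein genes Igfbp4 at 452 ± 75.3, Igfbp7 at 257 ± 52.9 and Igfbp6 at 7.98 ± 4.41. These levels are not corrected for transcript length.

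The tests in the paragraphs that follow were chosen after the results were seen, except those of the second microglial list and of read depth in replicate 3. The design names no group that separates the libraries, so no biological explanation was tested against one. Replicates 2 and 3 shared the sex-linked pattern given in the report (Kdm5d at 539 and 536) and replicate 1 differed from both, so sex does not separate replicate 2 or replicate 3 from the others. It stays open, as untested, for the microglial genes of replicate 1.

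Ttr was higher in replicate 2 than in replicates 1 and 3. Read sampling is argued against by the chi-square test of its reads (adjusted p = 8.31e-215). Choroid plexus cells carried over in replicate 2 may be a source, and Slc4a5 had 9 reads there against 0 and 0 in the shallower libraries, but Clic6, at a normalized count of 17.9 against 8.95 and 11.96, did not pass the chi-square test of its reads (adjusted p = 0.149). Over the 9 other choroid plexus genes the median log2 ratio of replicate 2 to the others was -0.00529, with an SD of 1.08 and members going both ways, and Folr1 was at 334 against 425 and 386. This stays open because the other members have a high baseline or lie near the floor.

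Ciliated-cell genes were lower in replicate 2 and microglial genes higher in replicate 1. Exon length correlated across genes with the ratio of replicate 1 (Spearman's rho -0.260) and of replicate 2 (rho 0.216), but less the genes matched on length the ependymal list kept a median log2 ratio of -0.607 (from -0.65, SD 0.275 over 13 genes) and the microglial list one of 0.357 (from 0.43, SD 0.198 over 19 genes), which argues against a length trend as the whole cause. Fewer ciliated cells or less transcription of cilia genes in replicate 2 may account for the first part. There 76 genes outside the list, taken as axonemal by symbol only, had a median ratio of -0.442 (SD 0.424). The rule took symbols starting, for example, with Cfap, Dnah, Rsph, Tekt or Spag, and the function of each gene was not checked. Of these 63 were lowest in that library, against 3848 of all 13941 genes with a mean of 10 or more. More microglia in replicate 1 may account for the second, since 23 further microglial genes, 0 of them in another list and led by Lgmn at 6794 ± 683, Mpeg1 at 5922 ± 771 and Lyz2 at 3650 ± 1148, had a median ratio of 0.24 (SD 0.351) and 17 were highest there. A change of expression within microglia or ciliated cells was not separated from a change in their number.

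The genes Rpl22l1, Atp5mk, Shh, Snrpert and Lsm5, 5 with a mean of 100 or more, were over 2-fold higher in replicate 3 than in both other libraries. By the same rule 4 genes were higher in replicate 1 and 2 in replicate 2, so such genes were not particular to replicate 3. Another 6 genes were over 2-fold lower in replicate 3, with a median exon length of 1003.5 nucleotides. Simulated reads at these depths from equal means gave on average 0 genes over 2-fold higher in replicate 3, over 100 draws. At a mean of 100 or more, sampling alone rarely gives a 2-fold difference, and the draws held no other variation between libraries. They speak only against read sampling at the smaller depth of replicate 3, and other effects of depth were not tested. Spearman's rho across 10556 genes between exon length and the ratio of replicate 3 was 0.0818, which argues against a general rise of shorter genes. Genes matched on length had a median log2 ratio of at most 0.17 where these 5 had 1.25. The 5 were selected for a high ratio, so that gap cannot decide whether length contributed. The 5 genes were nonetheless short, with a median exon length of 1989 nucleotides against 4845 over all genes with a mean of 100 or more, and the 162 genes of up to 1000 nucleotides held 2 of them (1.23%) and had a median ratio of 0.09, while the 4298 genes of 4000 to 8000 nucleotides and the 2228 longer ones held 0. A difference between the animals or the cultures in these genes stays open as a hypothesis.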
